A study of Mus musculus with 8 samples.

How the data were processed

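RNA immunoprecipitation sequencing (RIP-seq) libraries were made from mouse placentas at E14.5. Per the labels' protocols, placentas were lysed in a buffer for double-stranded RNA immunoprecipitation, RNA was pulled down with an Mda5 antibody or IgG on Protein G beads, extracted with TRIzol, depleted of rRNA, fragmented and sequenced on a NovaSeq. Genotype, antibody and placenta code came from the sample titles. The 8 libraries fell into 4 groups (Adar f/f or PKO, each with IgG or Mda5) of 2 libraries, from placentas a8 and b9 (f/f) and a3 and b2 (PKO).

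The authors deposited 1 table of raw counts per gene for all 8 libraries, and 0 of its columns of per-sample values were left unused. The submitters' processing notes name FastQC, STAR 2.5.3a, edgeR and the mm39 genome, with no role or order; the counting tool, its annotation and whether it used strand are not given in the sources used here. In the counts, even values outnumbered odd ones at low levels (6850 against 3631 in the f/f IgG library of a8), so both mates of a read pair appear to have been counted. The lowest total over the 8 libraries was 11, so genes of lower total were not in the table. Beside the counts, the same table held the authors' comparison of Mda5 with IgG in PKO. Its deposited mean signal per gene equals the mean of the counts after division by median-of-ratios size factors, recomputed here. Its log2 fold changes and their standard errors were deposited by the authors for that comparison alone, with p-values and adjusted p-values, and the authors' tool for it is not given in the sources used here. This table was used only where it is named.

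Of the 32814 genes of the table, 1011 had an identifier but no name (0.04 to 0.05% of the counts of each library); they were kept, and are not named. A further 24 names were shared by 49 entries. Genomic spans came from RefSeq annotation of GRCm38.p6, another assembly than that of the counts, and were matched by symbol or synonym for 25402 genes of the table and 21350 of the 26170 tested; none of its coordinates is used. Histones, ribosomal proteins, prolactins, Psg, Ceacam, Gbp, Mx, Ifit, Oas, H2 and interferon genes have near-identical relatives or pseudogenes, and their counts are uncertain where the counting could split reads between copies. Kcnq1ot1, Airn, Egfros, the snoRNA host genes and other genes that overlap or oppose a neighbour are uncertain likewise, since reads of the neighbours cannot be told apart without strand.

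Total counts per library were 202978500 and 204623714 (f/f IgG, a8 and b9), 208080360 and 208356609 (f/f Mda5), 194024083 and 198341244 (PKO IgG, a3 and b2) and 208674049 and 206148354 (PKO Mda5). At this depth counting error is small for all but rare RNAs. Intervals (95%) and floors (3 counts per library) cover counting error only, since reads without molecular identifiers are not independent molecules. They take every count as independent. If both mates of a pair were counted, the intervals are too narrow and the bounds drawn from the floor too high. Replicate libraries were compared before they were averaged: the median chi-square per gene was 2.46, 1.83, 2.76 and 3.45 in the 4 groups in that order, against 0.91 for sampling noise with mates counted apart, so no pair was a repeat of 1 library.

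Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM normalization, and the robust quasi-likelihood test in 1 fit of the 4 groups with 4 residual degrees of freedom, with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. The common biological coefficient of variation was 0.062. CPM were computed after TMM scaling, with a prior count of 2 on the log scale. The 6 comparisons were Mda5 against IgG in PKO, in f/f and over both genotypes, the difference of these enrichments between genotypes (an interaction term), and PKO against f/f in Mda5 libraries and in IgG libraries. These comparisons, the tests, the alternatives, the lists and the rule for named genes were fixed before the data were examined.

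The 25 lists held interferon-stimulated genes, type I and III interferons, double-stranded RNA binding and sensing, the integrated stress response, the unfolded protein response, apoptosis with necroptosis and p53 targets, ADAR editing targets, mitochondrially encoded mRNAs, mitochondrially encoded rRNAs, small structured RNAs, long nuclear RNAs, ribosomal proteins, replication-dependent histones, syncytiotrophoblast, trophoblast giant cells, spongiotrophoblast with glycogen cells, decidua, endothelium, erythroid cells, macrophages, NK and T cells, neutrophils, yolk sac endoderm, Xist with Y-linked genes, and immediate-early genes. The interferon-stimulated list shared 11 genes with the double-stranded RNA list and 1 with the NK and T cell list, the editing targets 1 with the erythroid list, and the long nuclear RNAs 1 with the Xist and Y-linked list. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation; fry, which asks whether a list moves one way, was an alternative. Mitochondrial rRNAs, with 2 genes, were not tested with camera. Counts given as adjusted over the list alone repeat the Benjamini-Hochberg step over a list's own members.

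Named genes were Adar and Ifih1; per comparison the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 CPM, no overlap between the groups' libraries (for the interaction, both PKO placentas on one side of both f/f placentas) and a full symbol; up to 4 members of each list with the lowest p; and the 5 genes of highest mean CPM. Groups with all libraries at 0 are given as bounds, and f/f counts of 1 to 3 as a ratio with its counting interval.

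Because the Mda5 and IgG libraries of a code come from 1 animal, the codes pair the libraries. Over genes of at least 100, 1000 and 10000 counts on average (15384, 10766 and 4521 genes), the deviations of the paired libraries from their group means correlated across genes at 0.03, −0.02 and 0.02 in f/f. In PKO the values were −0.19, 0.10 and 0.19, so the sign of this measure, Pearson's r, depended on the genes taken. Spearman's rho was −0.05, −0.11 and −0.18 in f/f and 0.02, 0.17 and 0.23 in PKO. Fits with the placenta as a block were run for the comparisons between antibodies and for the interaction; between genotypes the placenta lies within a genotype, so it entered as a random block in limma-voom (duplicateCorrelation). Lists were not tested with the block between genotypes. Other alternatives were DESeq2 size factors, library totals, no filter, a stricter filter (10 counts in 4 libraries), DESeq2 1.42.0, limma-voom, only the compared groups in the fit, leaving out mitochondrial, rRNA and globin genes, leaving out each library or placenta, and an adjusted p under 0.1. TMM factors taken from genes of at least 1 CPM, with all 26170 genes tested, were added after the data were seen, with others named in the closing section. Pseudocount alternatives were planned for normalized values and were not run, since the values are counts.

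The edgeR step was tested on simulated counts over 25121 genes before use, with changes planted in the PKO Mda5 libraries. Each fold change was planted in 50 genes, all with a mean of at least 1 CPM, and all other genes were unchanged. In the data 45.8% of genes were called for Mda5 against IgG in PKO, so the simulation differs from them and says nothing on genes under 1 CPM. For Mda5 against IgG in PKO it recovered 56% of genes changed 1.25-fold, 96% at 1.5-fold and 100% at 2-fold, and for the interaction 20%, 76% and 98%. For PKO against f/f in Mda5 libraries the shares were 66%, 90% and 100%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.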

Results

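RNA recovered with Mda5 was measured by immunoprecipitation and sequencing in mouse placentas at E14.5. Mda5, the product of Ifih1, is a cytoplasmic sensor of double-stranded RNA. Adar encodes an enzyme that converts adenosine to inosine in double-stranded RNA. The placentas were Adar f/f (a8 and b9) or Adar ko (a3 and b2), named AdarPKO in the series' design and PKO here. Each placenta gave 1 library with an Mda5 antibody and 1 library with IgG, which made 8 libraries in 4 groups of 2. Total counts per library lay between 194024083 and 208674049. The 10 most abundant genes took 5.1 to 8.4% of the counts, and mitochondrially encoded genes 0.029 to 0.093%. Of the 32814 genes in the deposited table, 26170 passed the filter on low counts and were tested. The first principal component of the log2 levels, with 67.9% of the variance, parted the genotypes. The second, with 29.2%, parted the antibodies. Input RNA named in the labels was not analysed here.

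Adar itself was counted in every library. Its level was 105 and 103 CPM (TMM-scaled counts relative to library size) in the f/f IgG libraries and 78.1 and 78.2 CPM in the f/f Mda5 libraries. In PKO it was 80.6 and 86.7 CPM with IgG and 75.2 and 78.4 CPM with Mda5. Between genotypes Adar was lower in IgG libraries, with a log2 fold change of −0.31 ± 0.06 (SE, 2 libraries per group, edgeR adjusted p = 6.38e-05). In Mda5 libraries its value was −0.03 ± 0.06 (edgeR adjusted p = 0.727). Scaling to library totals turned the first of these to 0.05, and gave 0.29 in Mda5 libraries (edgeR adjusted p = 9.13e-05). Counts over the whole gene cannot show which exons were read, so the level of Adar does not check the genotype labels.

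Ifih1 stood at 81.2 and 90.6 CPM in the f/f IgG libraries and 270 and 234 CPM in the f/f Mda5 libraries. In PKO it stood at 176 and 184 CPM with IgG and 491 and 658 CPM with Mda5. Ifih1 mRNA was thus higher with the Mda5 antibody in all 4 placentas. The log2 fold change was 1.67 ± 0.15 in PKO (edgeR adjusted p = 0.000154) and 1.55 ± 0.15 in f/f (edgeR adjusted p = 0.000184). Ifih1 was also higher in PKO than in f/f, by 1.19 ± 0.15 in Mda5 and 1.07 ± 0.15 in IgG libraries.

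**Figure D1:**
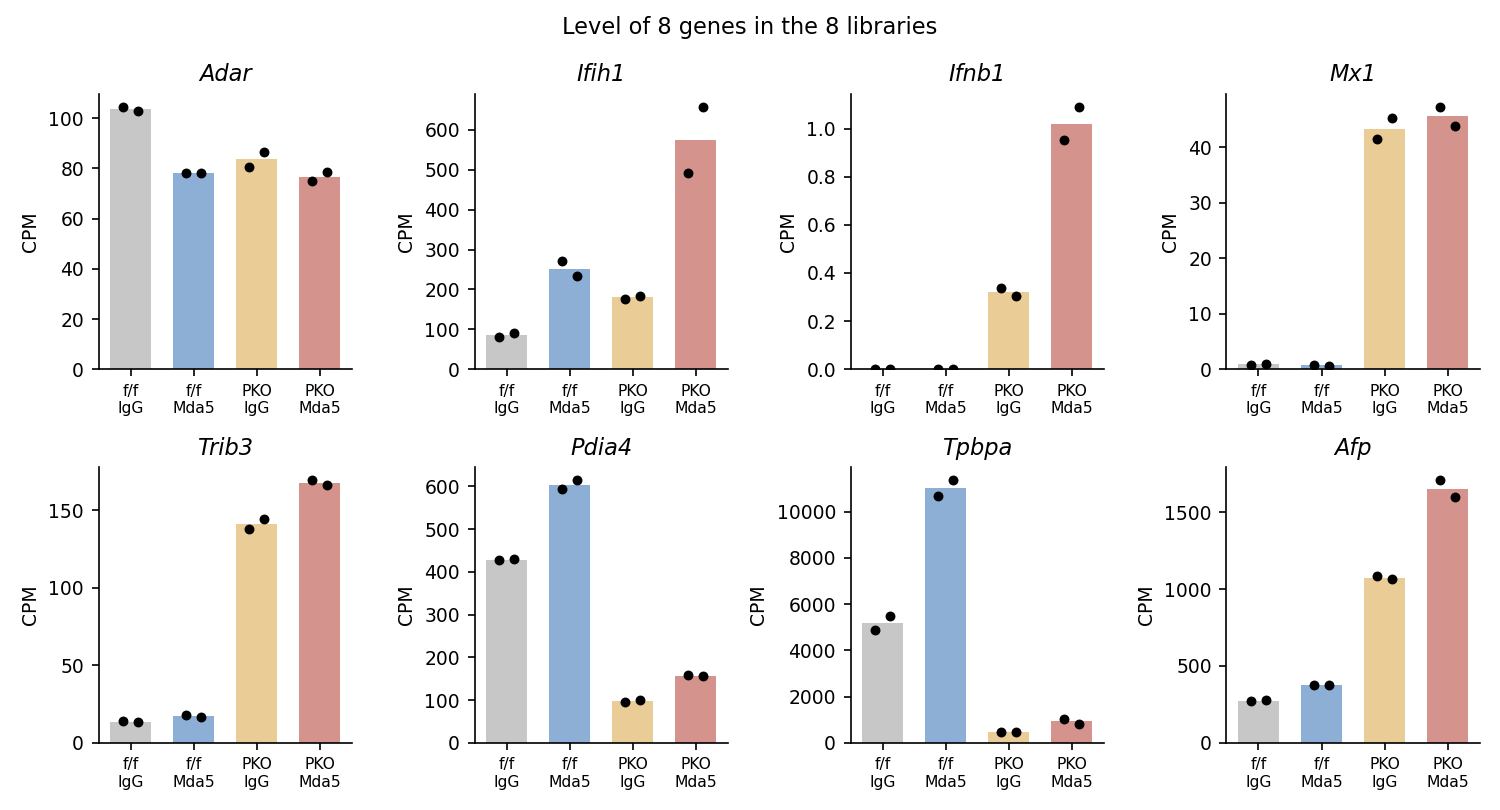
Level of 8 genes (TMM-scaled CPM, linear axes from 0, a separate scale for each gene); bars are the mean of 2 libraries per group and dots the single libraries. Ifnb1 is at 0 in the 4 f/f libraries, Adar lies between 75.2 and 105 CPM in all 8, and Tpbpa and Afp part the genotypes in opposite directions.

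The first question was which RNAs the Mda5 antibody recovered above IgG in PKO placentas. Armh4 had the highest enrichment, at 27.9 ± 0.373 CPM (SD, n = 2) with Mda5 against 2.82 ± 0.156 CPM with IgG. Its log2 fold change was 3.31 ± 0.07 (SE, edgeR adjusted p = 1.15e-17). Bik and Bok, proapoptotic members of the Bcl2 family, followed with 2.71 ± 0.12 (edgeR adjusted p = 2.02e-10) and 2.46 ± 0.14 (edgeR adjusted p = 3.19e-06). Fdft1, the squalene synthase of sterol synthesis, rose by 2.00 ± 0.09 and the mitochondrial ribosomal protein gene Mrps18a by 1.94 ± 0.06. The transcriptional repressor gene Bcl6b rose by 1.82 ± 0.18, Gde1 by 1.77 ± 0.09 and Cryz by 1.69 ± 0.08.

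At the other end in PKO stood the small nucleolar RNA Snord17 (−2.36 ± 0.16, edgeR adjusted p = 8.12e-08) and the small Cajal body RNA Scarna2 (−1.93 ± 0.08). Ttn, which encodes titin, was at −1.85 ± 0.08 (edgeR adjusted p = 3.64e-12), with Lrrtm2 at −2.10 ± 0.36 and Celf3 at −1.80 ± 0.32. B3galt2 (−2.17 ± 0.46), Pprc1 (−1.95 ± 0.52) and Kcnq1ot1 (−1.89 ± 0.46) also passed, at edgeR adjusted p of 0.0173, 0.0412 and 0.0318. With the placenta as a block these became 0.0832, 0.168 and 0.128. Adar was not called (−0.12 ± 0.06, edgeR adjusted p = 0.0716), but was with library totals (0.00721).

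Genes were grouped by lists fixed before the data were examined. Of 47 tested mRNAs of replication-dependent histones, 45 were higher with Mda5 in PKO and none lower (adjusted over the list alone, 45). H3c10 rose by 1.36 ± 0.06 and H3c7 by 1.26 ± 0.06. For the histone list, camera gave adjusted p = 1.73e-56 (adjusted p = 0.0889 with an estimated correlation). Ribosomal protein mRNAs were higher for 58 of 75 (adjusted over the list alone, 60 higher and 1 lower), among them Rpl36 at 1.29 ± 0.07. On this list camera gave adjusted p = 2.51e-15 (adjusted p = 0.303 with an estimated correlation).

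Mitochondrially encoded mRNAs went the other way in PKO. All 11 tested were lower, also when adjusted over the list alone, with mt-Nd4 at −1.71 ± 0.10 and mt-Nd1 at −0.72 ± 0.07. This list call held both ways (camera adjusted p = 1.41e-10, adjusted p = 0.0492 with an estimated correlation). The mitochondrial rRNAs mt-Rnr2 (−1.74 ± 0.39) and mt-Rnr1 (−0.79 ± 0.38) had edgeR adjusted p of 0.0251 and 0.12. With the placenta as a block these were 0.118 and 0.00386. The RNA was depleted of rRNA before sequencing. What that step left of these 2 rRNAs cannot be told apart from what the antibody recovered, here and in the other comparisons. Of 21 long nuclear RNAs, 14 were lower and 1 higher (adjusted over the list alone, 16 and 1), among them Airn at −1.20 ± 0.10 and Norad at −0.53 ± 0.06. For long nuclear RNAs, camera gave adjusted p = 1.24e-06 (adjusted p = 0.0889 with an estimated correlation). That is only the name of the list. Where its members, such as Norad, lie in the cell was not measured, so its counts here and below say nothing on nuclear RNA as such. Small structured RNAs were lower for 7 of 17 and higher for 0 in both adjustments, with Scarna6 at −1.75 ± 0.09. The camera adjusted p of this list was 4.98e-07 (adjusted p = 0.0889 with an estimated correlation).

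Interferon-stimulated mRNAs were higher with Mda5 in PKO for 41 of 59 tested members and lower for 4 (adjusted over the list alone, 42 and 5). With TMM factors from genes of at least 1 CPM they numbered 27 and 9. Bst2, a membrane tether of budding virions, rose by 0.95 ± 0.06 and the ubiquitin-like Isg15 by 0.76 ± 0.07. Ly6e rose by 0.75 ± 0.07 and the oligoadenylate synthetase gene Oas1a by 0.51 ± 0.06. The list had a camera adjusted p of 7.26e-08 (adjusted p = 0.196 with an estimated correlation). Of 6 tested interferon genes, 4 were higher and 0 lower in both adjustments (camera adjusted p = 0.114). Ifnb1, which encodes interferon beta, had 76 and 68 counts with IgG and 218 and 248 with Mda5 (1.67 ± 0.27, edgeR adjusted p = 6.31e-05). The other 3 depended on single libraries. Without the Mda5 library of a3 the edgeR adjusted p was 0.0685 for Ifne, 0.153 for Ifnl2 and 0.374 for Ifnl3. Without the IgG library of a3 it was 0.0637 for Ifnl2 and 0.196 for Ifnl3, and without that of b2 it was 0.0918 and 0.106. Ifnl3 also lost its call with the block (0.0818), and with TMM factors taken from genes of at least 1 CPM both Ifnl2 (0.0537) and Ifnl3 (0.0985) lost theirs.

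Genes of double-stranded RNA binding and sensing split in PKO, with 11 higher and 6 lower of 31 (adjusted over the list alone, 12 and 6; camera adjusted p = 0.509). The balance turned with library totals (9 and 11) and with TMM factors from genes of at least 1 CPM (7 and 15). Examples were Irf3 at 0.37 ± 0.06, Strbp at −0.48 ± 0.06 and Dicer1 at −0.36 ± 0.05. Known ADAR editing targets also split, with 6 higher and 4 lower of 22 in both adjustments, and 4 and 5, then 3 and 6, with these 2 scalings. Igfbp7 was at 0.78 ± 0.06, Flnb at −0.90 ± 0.06 and Flna at −0.73 ± 0.06. The median of the editing targets was 0.04 and their mean −0.05 (camera adjusted p = 0.812).

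Stress and death genes were mostly on the Mda5 side in PKO. So were genes of 5 to 100 CPM in general, with medians of 0.23 at 5 to 20 CPM and 0.16 at 20 to 100 CPM. The list medians were 0.25 (integrated stress response), 0.45 (unfolded protein response), 0.29 (apoptosis) and 0.18 (immediate-early genes). In the integrated stress response, phosphorylated eIF2α raises translation of Atf4. Of its 44 genes, 27 were higher and 3 lower in both adjustments (17 and 6 with TMM factors from genes of at least 1 CPM), with Atf4 at 0.69 ± 0.05, Ddit4 at 0.68 ± 0.05 and Sesn2 at 1.10 ± 0.09. The list had a camera adjusted p of 3.11e-05 (adjusted p = 0.0889 with an estimated correlation). Unfolded protein response genes were higher for 19 of 22 (adjusted over the list alone, 20), such as the chaperone genes Hsp90b1 at 0.86 ± 0.06 and Pdia3 at 0.84 ± 0.06. On that list camera gave adjusted p = 2.95e-12 (adjusted p = 0.0994 with an estimated correlation). For apoptosis, necroptosis and p53 targets, 12 of 22 were higher and 3 lower (adjusted over the list alone, 14 and 3; 11 and 5 with the same TMM factors), among them Bbc3 at 0.85 ± 0.08. Camera gave adjusted p = 0.0201 for it (adjusted p = 0.303 with an estimated correlation). Immediate-early genes, which also mark tissue handling, were higher for 11 of 18 and lower for 2 (adjusted over the list alone, 12 and 2; 7 and 2 with those factors), with Zfp36 at 0.63 ± 0.06. Camera's adjusted p of 0.0239 became 0.0619 without the IgG library of a3 (adjusted p = 0.303 with an estimated correlation).

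Markers of most placental cell types were recovered with Mda5 above IgG in PKO, as were protein-coding genes of short genomic span in general. The shortest of 5 bins of these genes had a median of 0.405, with quartiles of 0.225 and 0.617. The lists were not tested with the trend on span removed. Giant cell genes were higher for 18 of 20 and lower for 1 (adjusted over the list alone, 19 and 1). Spongiotrophoblast and glycogen cell genes were higher for 23 of 26 (adjusted over the list alone, 24) and decidual genes for 16 of 17 in both adjustments. Prl4a1 stood at 0.95 ± 0.06, Prl8a8 at 1.09 ± 0.08, Prl8a2 at 1.24 ± 0.07 and Lum at 1.04 ± 0.07. Camera adjusted p for these 3 lists were 9.41e-19, 4.48e-19 and 1.18e-15 (adjusted p = 0.0889, 0.0925 and 0.0889 with an estimated correlation). Endothelial genes were higher for 15 of 17 in both adjustments, with the junction gene Esam at 1.14 ± 0.06 and Plvap at 0.88 ± 0.05. NK and T cell genes were higher for 11 of 16 in both adjustments, with granzyme Gzmf at 1.14 ± 0.07 and perforin Prf1 at 1.02 ± 0.06. Both of these calls held (camera adjusted p = 6.79e-14 and 7.96e-10, adjusted p = 0.028 and 0.0492 with an estimated correlation).

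Blood and yolk sac markers were also higher with Mda5 in PKO. The counts were 10 of 16 erythroid genes with 1 lower, 11 of 15 macrophage genes, 6 of 12 neutrophil genes and 12 of 13 yolk sac endoderm genes, all unchanged when adjusted over the list alone. Hba-a1 stood at 1.08 ± 0.08, C1qb at 0.99 ± 0.08, S100a8 at 1.33 ± 0.08 and Apoa4 at 0.94 ± 0.07. Camera adjusted p for these 4 lists were 3.16e-05, 2.8e-06, 0.0021 and 1.41e-10 (adjusted p = 0.196, 0.0889, 0.196 and 0.0889 with an estimated correlation). Syncytiotrophoblast genes had 5 higher and 2 lower of 16 in both adjustments (3 and 3 with library totals, 2 and 3 with TMM factors from genes of at least 1 CPM; camera adjusted p = 0.469), with Slc16a3 at 0.63 ± 0.06 and Igf2bp1 at −0.41 ± 0.06. Among Xist and 4 Y-linked genes 3 were lower (adjusted over the list alone, 4), with Ddx3y at −0.30 ± 0.06 and Kdm5d at −0.42 ± 0.10. The call of this list (camera adjusted p = 0.0481) ended with the block (0.0514) and with an estimated correlation (adjusted p = 0.253). Kdm5d lost its own call without the IgG library of a3 (edgeR adjusted p = 0.0895). Of the 5 most abundant genes, Tpbpa (1.02 ± 0.11) and Actb (0.42 ± 0.06) were higher and Peg10 (−0.45 ± 0.06), Pappa2 (−0.24 ± 0.06) and Fn1 (−0.21 ± 0.06) lower. Fn1 lost its call without the IgG library of b2 (edgeR adjusted p = 0.182).

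In total, edgeR's quasi-likelihood test called 6721 genes higher and 5252 lower with Mda5 than with IgG in PKO. A change of at least 2-fold was reached by 318 of the higher and 2897 of the lower genes, and 2501 of the latter had predicted or unnamed symbols. At a mean of 1 CPM or more the 2-fold calls were 169 and 135. Scaling to library totals gave 5711 higher and 5998 lower. TMM factors taken from genes of at least 1 CPM gave 4220 and 7477, with a median over all genes of −0.15 instead of 0.00. Without both libraries of a3 the calls numbered 4594 and 2084. In the authors' deposited table of this same comparison, 45 genes were marked up and 1593 down, the smallest absolute log2 fold change among them being 1.501. That table has 10368 genes with an adjusted p below 0.05, of which 10332 passed here too, in the same direction. Its log2 fold changes, from the same counts, correlated with those given here across genes at r = 0.9997. Of 16711 protein-coding genes, edgeR called 6469 higher and 2180 lower in PKO. Camera compares a list with all other genes, and 8788 of the 26170 tested lay under 0.25 CPM, with a median of −0.63. A list of expressed mRNAs can thus be called higher at a level that other expressed mRNAs share.

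The same contrast in f/f placentas showed which RNAs were recovered with Mda5 without the PKO genotype. Armh4 was again the highest (3.38 ± 0.07, edgeR adjusted p = 5.01e-18), with Bik at 2.48 ± 0.13, Fdft1 at 2.12 ± 0.09 and Mrps18a at 2.03 ± 0.06. Bok followed at 1.97 ± 0.14 and Gde1 at 1.72 ± 0.09. Phyh, an enzyme of peroxisomal fatty acid oxidation, rose by 1.64 ± 0.07 (edgeR adjusted p = 3.96e-13) and Fkbp11 by 1.64 ± 0.06. Among the lowest were Ttn (−2.23 ± 0.09, edgeR adjusted p = 4.27e-13), Scarna2 (−2.18 ± 0.09) and the mitochondrial mRNA mt-Nd4 (−2.04 ± 0.10). Pprc1 (−2.67 ± 0.53), Fcgr1 (−2.25 ± 0.54), Kcnq1ot1 (−2.08 ± 0.48), B3galt2 (−2.01 ± 0.54) and mt-Rnr2 (−2.00 ± 0.39) passed as well. With the placenta as a block their edgeR adjusted p were 0.0907, 0.1, 0.125, 0.125 and 0.0897. Adar was lower with Mda5 (−0.41 ± 0.06, edgeR adjusted p = 3.01e-06).

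Histone mRNAs were higher in f/f for 45 of 47 (adjusted over the list alone, 46), with H3c7 at 1.39 ± 0.06. Ribosomal protein mRNAs were higher for 67 of 75 (adjusted over the list alone, 72), with Rpl5 at 1.56 ± 0.08. Camera adjusted p for these 2 lists were 5.8e-70 and 9.05e-19 (adjusted p = 0.115 and 0.316 with an estimated correlation). Mitochondrial mRNAs were lower for 10 of 11, long nuclear RNAs for 12 of 21 with 2 higher, and small structured RNAs for 6 of 17 with 1 higher. Adjusted over the list alone, 10, 16 and 6 were lower. Among them were mt-Nd1 at −0.87 ± 0.07, H19 at −0.84 ± 0.08 and Scarna6 at −1.80 ± 0.09. Their lists had camera adjusted p of 3.17e-12, 3.33e-05 and 0.000326 (adjusted p = 0.0603, 0.125 and 0.176 with an estimated correlation). Both mitochondrial rRNAs were lower, with the same limit from rRNA depletion as in PKO.

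Interferon-stimulated genes had 28 higher and 9 lower of 59 in f/f (adjusted over the list alone, 30 and 9; 21 and 14 with TMM factors from genes of at least 1 CPM), with Bst2 at 1.12 ± 0.06 and Isg20 at 0.75 ± 0.07. The list had a camera adjusted p of 0.00538 (adjusted p = 0.452 with an estimated correlation). Among interferon genes 1 of 6, Ifnk, was higher in both adjustments (0.81 ± 0.19; camera adjusted p = 0.764 for the list), and 4 others had 0 to 2 counts in every f/f library. Ifnk lost its call without both libraries of b9 (edgeR adjusted p = 0.18) and with the length offset (0.14). Genes of double-stranded RNA binding had 7 higher and 11 lower of 31 (adjusted over the list alone, 7 and 12), for example Dhx9 at −0.55 ± 0.05. Editing targets had 6 higher and 4 lower of 22 in both adjustments, and 4 and 4 with TMM factors from genes of at least 1 CPM, with Flnb at −0.89 ± 0.06. Neither list was called (camera adjusted p = 0.394 and 0.812), and median and mean differed in sign in both (−0.06 and 0.01 for double-stranded RNA binding, 0.06 and −0.05 for editing targets). For the integrated stress response the counts were 27 higher and 6 lower of 44, and for the unfolded protein response 19 and 1 of 22, in both adjustments. Their camera adjusted p were 0.00188 and 4.03e-09 (adjusted p = 0.176 for each with an estimated correlation). The apoptosis list (11 higher and 2 lower of 22) and the immediate-early list (9 higher of 18) had the same counts when adjusted over the list alone. They missed the threshold (camera adjusted p = 0.0851 and 0.0592). With TMM factors from genes of at least 1 CPM the counts were 7 and 18 for double-stranded RNA binding, 19 and 7 for the integrated stress response, 10 and 5 for apoptosis and 7 and 3 for immediate-early genes.

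Cell type markers in f/f gave 18 of 20 giant cell genes higher and 1 lower, and 23 of 26 spongiotrophoblast and glycogen cell genes higher. For decidua 13 of 17 were higher and 1 lower, and for yolk sac endoderm 11 of 13 and 1, all in both adjustments. Camera adjusted p for these 4 lists were 6.79e-16, 1.51e-15, 9.24e-07 and 2.46e-06 (adjusted p = 0.158, 0.176, 0.255 and 0.176 with an estimated correlation). Endothelial genes had 13 higher and 2 lower of 17 (adjusted over the list alone, 13 and 3; 8 and 3 with TMM factors from genes of at least 1 CPM), with Esam at 0.97 ± 0.06. Erythroid genes had 10 and 1 of 16, macrophage genes 10 and 1 of 15, NK and T cell genes 9 and 0 of 16 and neutrophil genes 6 and 1 of 12, in both adjustments. From endothelium to neutrophils the camera adjusted p were 9.81e-05, 0.000326, 0.00337, 1.2e-05 and 0.0208 (adjusted p = 0.115, 0.284, 0.251, 0.115 and 0.316 with an estimated correlation). Syncytiotrophoblast genes had 4 higher and 5 lower of 16 in both adjustments (2 and 7 with those factors), and Xist with the Y-linked genes 1 and 3 of 5 (adjusted over the list alone, 1 and 4). Neither was called as a list (camera adjusted p = 0.754 and 0.374), the syncytiotrophoblast median being 0.02 and the mean −0.03.

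Across the genome 6577 genes were higher and 5236 lower with Mda5 in f/f by edgeR. At least 2-fold changes numbered 451 and 2215, of which 241 and 176 were at a mean of 1 CPM or more. Without both libraries of a8 the calls were 4483 and 3217, and with TMM factors from genes of at least 1 CPM 5152 and 6528. Of 16711 protein-coding genes, edgeR called 6215 higher and 2989 lower in f/f. Over all genes the f/f median was 0.24 at 5 to 20 CPM and 0.14 at 20 to 100 CPM, against 0.18 for interferon-stimulated genes. The genotypes' comparisons share no library. Across the 12402 genes of at least 2 CPM their log2 fold changes correlated at r = 0.916, with a major-axis slope of 0.831 for PKO on f/f; genes are not independent replicates. Over all 26170 tested genes r was 0.687, and both tests called 5456 genes higher and 3580 lower. Independent lists would share 1689 and 1051, and 28 genes were called in opposite directions. Among the 12402 genes alone, both tests called 5112 higher and 1790 lower, against 2820 and 443 for independent lists, with 22 opposite.

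**Figure D2:**
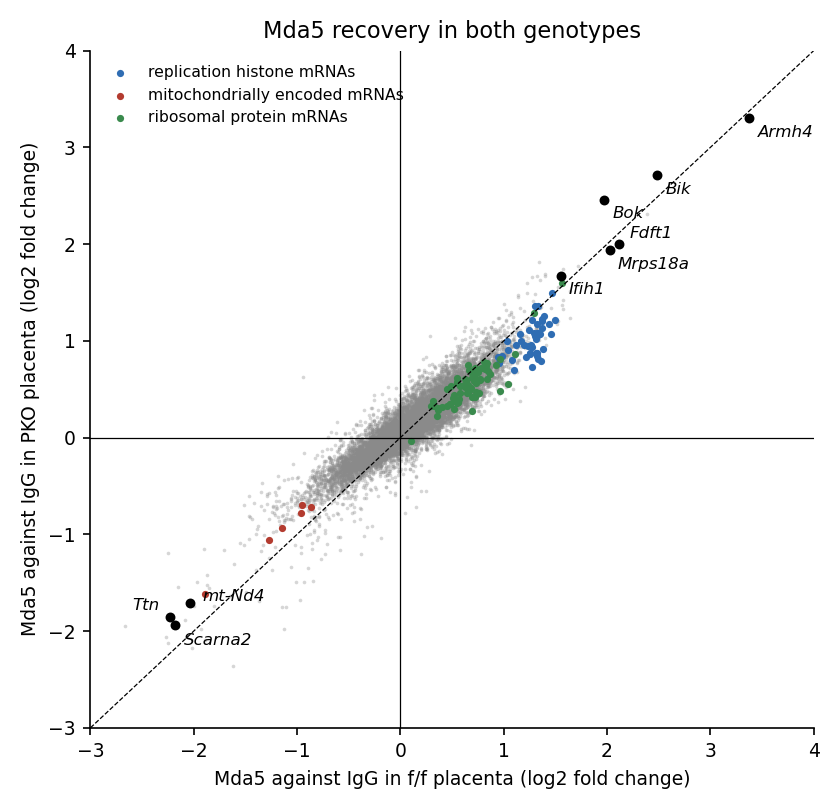
Log2 fold change of Mda5 against IgG in PKO placentas (vertical axis) against that in f/f placentas (horizontal axis), 1 dot per gene of at least 2 CPM, with the line of equality dashed. Armh4 is highest in both genotypes, histone and ribosomal protein mRNAs lie mostly on the enriched side, and mitochondrially encoded mRNAs on the depleted side.

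With all 8 libraries and both genotypes averaged, the Mda5 antibody enriched Armh4 most (3.34 ± 0.05, edgeR adjusted p = 6.78e-21). Bik (2.60 ± 0.09), Bok (2.22 ± 0.10), Fdft1 (2.06 ± 0.06), Mrps18a (1.98 ± 0.04) and Gde1 (1.75 ± 0.06) followed. Ifih1 (1.61 ± 0.11, edgeR adjusted p = 1.59e-05) and the metallothionein gene Mt2 (1.59 ± 0.16) came next. Scarna2 (−2.06 ± 0.06), Ttn (−2.04 ± 0.06), mt-Nd4 (−1.87 ± 0.07), Insyn2a (−1.83 ± 0.16) and Scarna6 (−1.77 ± 0.06) were among the lowest. So were B3galt2 (−2.09 ± 0.35), mt-Rnr2 (−1.87 ± 0.28) and Pprc1 (−2.31 ± 0.37), the last with an edgeR adjusted p of 0.00658 that became 0.0557 with the block. Adar was lower with Mda5 (−0.27 ± 0.04, edgeR adjusted p = 5.04e-06).

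Histone mRNAs had 45 of 47 higher over both genotypes, with a median of 1.11 and the same count when adjusted over the list alone (camera adjusted p = 1.95e-67, adjusted p = 0.106 with an estimated correlation). Mitochondrial mRNAs had 11 of 11 lower in both adjustments, with a median of −1.33 (camera adjusted p = 5.35e-12, adjusted p = 0.0367 with an estimated correlation). Endothelial genes had 14 of 17 higher (adjusted over the list alone, 15 higher and 1 lower; camera adjusted p = 7.38e-09, adjusted p = 0.0367 with an estimated correlation). In total 7949 genes were higher and 7018 lower by edgeR, and 7367 and 7568 with library totals. With TMM factors from genes of at least 1 CPM these were 5752 and 9120. Recovery fell with the genomic span of the gene. From the shortest to the longest of 5 bins of 11968 protein-coding genes, the median log2 fold change went from 0.41 to −0.07 in PKO and from 0.48 to −0.17 in f/f. Spearman's rho with span, across genes, was −0.50 and −0.54.

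**Figure D3:**
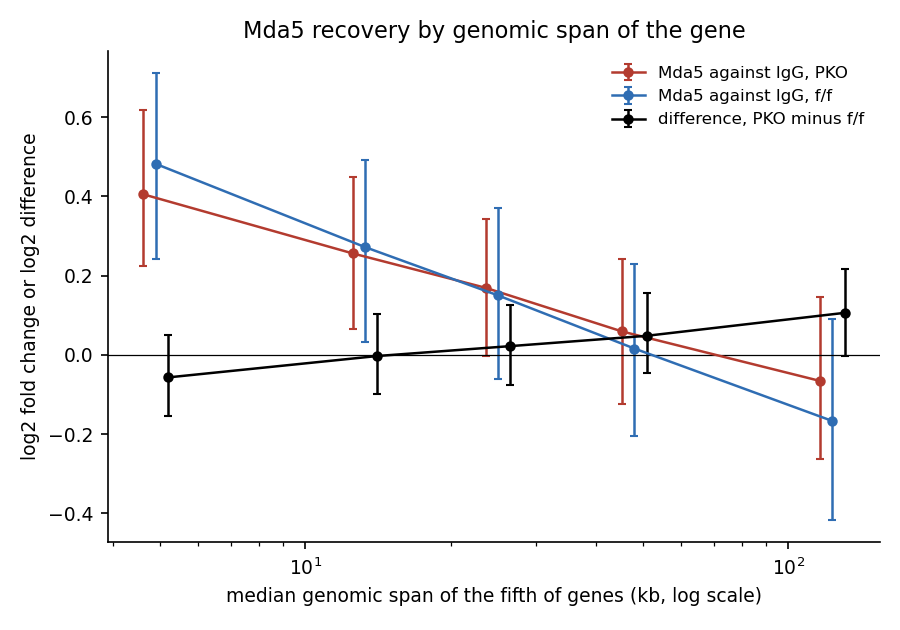
Median log2 fold change (points) with quartiles (bars) in 5 equal bins of 11968 protein-coding genes against the median genomic span of the bin in kb (log axis, points shifted sideways for legibility). Both genotypes fall from the shortest to the longest bin, and the difference rises from −0.06 to 0.11.

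The difference of Mda5 enrichment between PKO and f/f asks whether the Adar genotype altered what the Mda5 antibody recovered, and few genes passed its test. The highest differences were those of H2-T24, a nonclassical major histocompatibility class I gene (log2 difference 0.87 ± 0.11, edgeR adjusted p = 0.000832), and Col4a5, a chain of basement membrane collagen (0.86 ± 0.17, edgeR adjusted p = 0.0248). Ksr2 (0.83 ± 0.17), the B cell transcription factor gene Pax5 (0.79 ± 0.15), Hipk2 (0.78 ± 0.13), Arnt2 (0.78 ± 0.13), Zfp469 (0.77 ± 0.14) and Dnah10 (0.76 ± 0.15) followed. A higher difference can be a stronger recovery or a weaker depletion in PKO. H2-T24 was an example of weaker depletion, with a log2 fold change of −1.34 in f/f and −0.90 over both genotypes. The lowest were Slc6a16 (−1.68 ± 0.35, edgeR adjusted p = 0.0237), Cnpy1 (−1.33 ± 0.31), Snhg20 (−1.17 ± 0.24) and Egfros (−0.87 ± 0.18). Megf11 (−0.86 ± 0.15), Pfdn4 (−0.79 ± 0.19), Cox17 (−0.76 ± 0.15) and Rbm4b (−0.62 ± 0.15) were lower as well, the last without a call under the block (edgeR adjusted p = 0.0552). Without the Mda5 library of b9, every gene named as called in this comparison lost its call except H2-T24 and Ifit1. The edgeR adjusted p was then 0.0594 for Mmrn2 to 0.292 for Pfdn4. Leaving out any other single library, except the Mda5 library of a3, also ended some of these calls. TMM factors taken from genes of at least 1 CPM ended 12 of them, among others those of Col4a5 (edgeR adjusted p = 0.0836), Kdr (0.104) and Plvap (0.108).

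Interferon-stimulated genes had 4 of 59 with a higher difference and none lower (adjusted over the list alone, 7). The 4 were Ifit1 at 0.56 ± 0.09 (edgeR adjusted p = 0.00682), Oas3 at 0.58 ± 0.12 (edgeR adjusted p = 0.0244), Lgals3bp at 0.35 ± 0.08 and Dtx3l at 0.34 ± 0.08. With library totals 2 of the 59 were higher, and 2 with TMM factors from genes of at least 1 CPM. The median difference of this list was 0.09 (camera adjusted p = 0.000816, adjusted p = 0.626 with an estimated correlation). Double-stranded RNA binding genes had 1 of 31 higher, Oas3 (adjusted over the list alone, 3), with a median of 0.09. Their camera adjusted p of 0.00724 was lost with library totals (0.0646), without the IgG library of b9 (0.0588) and with an estimated correlation (adjusted p = 0.626). Endothelial genes had 4 of 17 higher (adjusted over the list alone, 10), namely Mmrn2 at 0.52 ± 0.09, Robo4 at 0.50 ± 0.09, the VEGF receptor gene Kdr at 0.39 ± 0.09 and Plvap at 0.32 ± 0.08. With library totals 2 of the 17 were higher, and 2 with TMM factors from genes of at least 1 CPM. The endothelial median was 0.23 (camera adjusted p = 1e-08, adjusted p = 0.0651 with an estimated correlation). No decidual gene passed alone by edgeR (adjusted over the list alone, 6). The decidual median was 0.20 (camera adjusted p = 1.06e-05, adjusted p = 0.626 with an estimated correlation).

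Histone mRNAs had 3 of 47 with a lower difference (adjusted over the list alone, 11), H4c14 at −0.57 ± 0.10, H4c12 at −0.45 ± 0.10 and H4c9 at −0.40 ± 0.10. The histone median was −0.26 (camera adjusted p = 5.95e-16, adjusted p = 0.626 with an estimated correlation). Ribosomal protein mRNAs had none called by edgeR in either adjustment, with a median of −0.11 (camera adjusted p = 0.00025). This list call was lost without the IgG library of a8 (0.0603) and with an estimated correlation (adjusted p = 0.97), and turned upward without the Mda5 library of b2 (0.00275). Single members called in other lists were the editing target Copa at 0.39 ± 0.08, the stress response gene Vldlr at 0.34 ± 0.08 and Prf1 at 0.40 ± 0.09. Their lists had camera adjusted p of 0.925, 0.554 and 0.086, with 1, 2 and 1 genes higher and 0, 2 and 0 lower when adjusted over the list alone. Fn1 (0.48 ± 0.09) and Pappa2 (0.37 ± 0.08) of the abundant genes passed too. In the 15 further lists tested with camera no member was called by edgeR, and the camera adjusted p lay between 0.0619 and 0.999. Adjusted over the list alone, 3 genes of the unfolded protein response were higher and 1 lower, and in each of the long nuclear, yolk sac and Xist lists 1 gene passed. For the interferon genes the list says nothing on this difference, since Ifnb1, Ifna4, Ifnl2 and Ifnl3 had 0 to 2 counts in every f/f library. Ifih1 (0.12 ± 0.21, edgeR adjusted p = 0.877) and Adar (0.29 ± 0.08, edgeR adjusted p = 0.0794) were not called.

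Over all genes, 278 differences were higher and 38 lower in PKO by edgeR, 1.2% of the genes tested, while 3425 had an unadjusted p below 0.05. The count was 928 with DESeq2, 150 (113 higher and 37 lower) with library totals, 132 (88 and 44) with TMM factors from genes of at least 1 CPM and 188 (117 and 71) when only those genes were fitted. It was 16 without the Mda5 library of b9 and 1612 without that of a3.

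Genotypes were compared within each antibody to describe the placentas themselves. Ifnb1 had 0 counts in the 4 f/f libraries. It was at least 62.9-fold higher in PKO Mda5 libraries and at least 19.5-fold higher in PKO IgG libraries, against a floor of 3 counts per library. Ifnl3, an interferon lambda gene, was at least 37.5-fold and 20.8-fold higher. Ifnl2 was higher by a ratio of 468 (95% counting interval 83.7 to 18510) and 137 (37.6 to 1136). If both mates of a pair were counted, these bounds are too high and the intervals too narrow. Ifnk fell in both antibodies (−1.42 ± 0.20 and −0.83 ± 0.20), and its IgG call was lost with library totals (edgeR adjusted p = 0.0615). Of 20 interferon genes listed, 9 were in the deposited table and 6 were tested. These had 5 higher and 1 lower in both antibodies and adjustments. Ifnb1, Ifna4, Ifnl2 and Ifnl3 had 0 to 2 counts in each f/f library and passed the filter through PKO libraries alone. The filter thus fixed their direction. Ifna4 was at least 4.45-fold and 1.89-fold higher, with the same limit on its bounds. On the 6 tested genes camera gave adjusted p = 0.00408 and 0.0174 (adjusted p = 0.185 and 0.242 with an estimated correlation), the second being 0.0968 with library totals. Those values share the limit set by the filter.

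Interferon-stimulated genes were higher in PKO for 56 of 59 and lower for 1 in both antibodies and both adjustments. The antiviral GTPase gene Mx1 stood at 6.03 ± 0.09 in Mda5 and 5.61 ± 0.09 in IgG libraries, and Mx2 at 5.12 ± 0.08 and 4.84 ± 0.08. Oas2 stood at 4.37 ± 0.09 and 4.23 ± 0.08 and Ifit2 at 4.14 ± 0.06 and 4.01 ± 0.06. This list held both ways (camera adjusted p = 2e-137 and 2.58e-125, adjusted p = 0.0178 and 0.0165 with an estimated correlation). Gbp2b, a guanylate-binding protein gene, had 0 and 2 counts in f/f Mda5 libraries and 4292 and 4224 in PKO, a ratio of 3447 (95% counting interval 954 to 28470). That interval, too, is too narrow if both mates of a pair were counted.

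Lists of stress genes moved in opposite directions between the genotypes. Of 44 genes of the integrated stress response, 34 were higher and 5 lower in Mda5 libraries and 37 and 3 in IgG libraries, in both adjustments. The pseudokinase gene Trib3 stood at 3.29 ± 0.06 and 3.39 ± 0.06 and asparagine synthetase Asns at 1.66 ± 0.06 and 1.67 ± 0.06. This list, too, held both ways (camera adjusted p = 3.65e-29 and 2e-27, adjusted p = 0.0178 and 0.0165 with an estimated correlation). Of 22 genes of the unfolded protein response, 21 were lower and none higher in both antibodies and adjustments. The disulfide isomerase genes Pdia4 and Pdia6 stood at −1.94 ± 0.05 and −1.68 ± 0.06 in Mda5 libraries. In IgG libraries Pdia4 stood at −2.12 ± 0.06. For the unfolded protein response, camera gave adjusted p = 2.48e-46 and 1.29e-48 (adjusted p = 0.0226 and 0.023 with an estimated correlation). Its medians were −1.52 and −1.67. In the same comparisons the medians of the giant cell list were −1.65 and −1.60 and of the spongiotrophoblast list −2.31 and −2.42.

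Apoptosis and p53 genes were higher in PKO for 17 of 22 and 16 of 22 and lower for 2 in each (adjusted over the list alone, 17 and 17 higher). Bbc3 stood at 1.87 ± 0.09 and 1.99 ± 0.09 and the cell cycle inhibitor gene Cdkn1a at 1.23 ± 0.06 and 1.28 ± 0.06. For this list camera gave adjusted p = 2.23e-06 and 5.8e-06 (adjusted p = 0.124 and 0.135 with an estimated correlation). Immediate-early genes were higher for 12 of 18 in each and lower for 3 and 4 (adjusted over the list alone, 12 and 4 in each), with Egr1 at 3.32 ± 0.09 and 3.43 ± 0.09. On these camera gave adjusted p = 9.4e-11 and 1.63e-10 (adjusted p = 0.0581 and 0.0681 with an estimated correlation). Double-stranded RNA binding genes had 16 of 31 higher in each and 8 and 10 lower in both adjustments, and with library totals 23 higher and 2 lower in Mda5 and 22 and 3 in IgG libraries. For this list the camera adjusted p were 7.71e-13 and 6.83e-10 (adjusted p = 0.049 and 0.0681 with an estimated correlation). Editing targets had 7 of 22 higher and 3 lower in Mda5 and 9 and 3 in IgG libraries, in both adjustments (12 and 2, and 13 and 3, with library totals; camera adjusted p = 0.761 and 0.726). Among them Flnb stood at 1.02 ± 0.06 and Cyfip2 at −1.16 ± 0.05 in Mda5 libraries.

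Trophoblast lineages moved apart, with the caution that prolactin, Psg, Ceacam and cathepsin genes are multigene families whose members can share reads. Spongiotrophoblast and glycogen cell genes were lower in PKO for 24 of 26 in Mda5 and 25 of 26 in IgG libraries with 1 higher in each, in both adjustments. The marker Tpbpa stood at −3.58 ± 0.12 and −3.51 ± 0.12 and Psg19 at −3.75 ± 0.06 and −3.77 ± 0.06. The list call held (camera adjusted p = 3.92e-81 and 2.23e-83, adjusted p = 0.0192 and 0.0218 with an estimated correlation). Giant cell genes were lower for 17 of 20 in Mda5 and 16 of 20 in IgG libraries, with 0 and 1 higher (adjusted over the list alone, 17 lower in each, with 1 and 2 higher). The cathepsin gene Ctsm stood at −3.78 ± 0.08 and −3.75 ± 0.08 and Prl8a9 at −2.93 ± 0.07 and −2.87 ± 0.07. The giant cell call held as well (camera adjusted p = 3.67e-38 and 2.4e-38, adjusted p = 0.0343 and 0.0362 with an estimated correlation). Syncytiotrophoblast genes split, with 7 higher and 5 lower of 16 in Mda5 and 7 and 6 in IgG libraries, in both adjustments (11 and 2, and 9 and 2, with library totals; camera adjusted p = 0.426 and 0.871), with a mean of −0.01 beside a median of 0.13 in IgG libraries. Of these Vegfa stood at 0.56 ± 0.05 and Slc40a1 at −0.59 ± 0.06 in Mda5 libraries.

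Yolk sac endoderm genes were higher in PKO for 13 of 13 in both antibodies and adjustments. Afp, which encodes alpha-fetoprotein, stood at 2.15 ± 0.06 and 1.97 ± 0.06 and albumin Alb at 2.23 ± 0.07 and 2.11 ± 0.07. This list held both ways (camera adjusted p = 5.46e-40 and 8.46e-37, adjusted p = 0.0192 and 0.0218 with an estimated correlation). Decidual genes were higher for 15 of 17 and 13 of 17 and lower for 2 in each, in both adjustments. Pgr stood at 1.53 ± 0.07 and 1.22 ± 0.07, but Hsd11b2 at −2.26 ± 0.06 and −2.21 ± 0.06. For decidua camera gave adjusted p = 2.15e-05 and 0.0094 (adjusted p = 0.301 and 0.575 with an estimated correlation).

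NK and T cell genes were higher in PKO for 9 of 16 and 8 of 16 and lower for 1 in each, in both adjustments, with Gzmf at 1.08 ± 0.07 and 0.82 ± 0.07. Their camera adjusted p were 0.00197 and 0.0202 (adjusted p = 0.124 and 0.227 with an estimated correlation). The second call ended without the IgG library of a8 (0.0707) or b2 (0.0599). Erythroid genes were lower for 10 of 16 and 12 of 16 and higher for 1 in each (adjusted over the list alone, 10 and 13 lower). The heme enzyme gene Alas2 stood at −0.91 ± 0.06 and −0.93 ± 0.06. For erythroid genes camera gave adjusted p = 0.000838 and 0.00061 (adjusted p = 0.301 and 0.302 with an estimated correlation). Endothelial genes had 9 higher and 3 lower of 17 in Mda5 and 4 and 5 in IgG libraries (14 and 1, and 13 and 3, with library totals). Macrophage genes had 9 and 4 of 15 and neutrophil genes 3 and 3 of 12 in each antibody (9 and 2, and 9 and 1, for macrophages with library totals, and 4 and 2, and 3 and 2, for neutrophils). These 3 lists had the same counts when adjusted over the list alone and were not called, at camera adjusted p of 0.245 and 0.511, 0.099 and 0.446, and 0.877 and 0.726.

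Among RNA classes, long nuclear RNAs were higher in PKO for 10 of 21 in Mda5 and 11 in IgG libraries and lower for 4 and 5 (adjusted over the list alone, 12 and 13 higher and 5 lower in each). The snoRNA host gene Snhg1 stood at 1.93 ± 0.09 and 2.08 ± 0.09. Camera gave adjusted p = 0.00154 and 0.001 for the list (adjusted p = 0.124 and 0.135 with an estimated correlation). Histone mRNAs were higher for 35 and 43 of 47 (adjusted over the list alone, 36 and 44), with H4c9 at 1.52 ± 0.07 and 1.92 ± 0.07. For the histone list, camera gave adjusted p = 2.96e-06 and 5.82e-13 (adjusted p = 0.486 and 0.306 with an estimated correlation). Mitochondrial mRNAs were lower for 7 and 9 of 11 in both adjustments, with mt-Nd1 at −0.78 ± 0.07 and −0.93 ± 0.07. Their camera adjusted p were 0.0251 and 0.00144 (adjusted p = 0.185 and 0.09 with an estimated correlation). In IgG libraries mt-Rnr1 was lower (−1.40 ± 0.35), a call lost without that of a3 (edgeR adjusted p = 0.06).

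Ribosomal protein mRNAs had 8 higher and 7 lower of 75 in Mda5 and 17 and 4 in IgG libraries (adjusted over the list alone, 7 and 5, and 17 and 4). With library totals they had 37 higher and 0 lower in Mda5 and 52 and 0 in IgG libraries by edgeR, while small structured RNAs had 5 and 2 and then 4 and 0, and Xist with the Y-linked genes 3 and 0 and then 4 and 0. Small structured RNAs had 2 and 2 of 17 and then 3 and 2 (adjusted over the list alone, 2 and 2, and 2 and 1). Xist with the Y-linked genes had 1 and 1 of 5 and then 1 and 0, in both adjustments. None of these 3 was called, at camera adjusted p of 0.761 and 0.13, 0.85 and 0.461, and 0.73 and 0.339. Further genes at the extremes in both antibodies were Gpr132, Slc6a21 and Avpr1b, at 4.26 or more on the log2 scale. At the lower end Tmem72, Ceacam14, Psg26, Prl8a8, Mlc1 and Neurog2 stood at −4.30 or below.

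**Figure D4:**
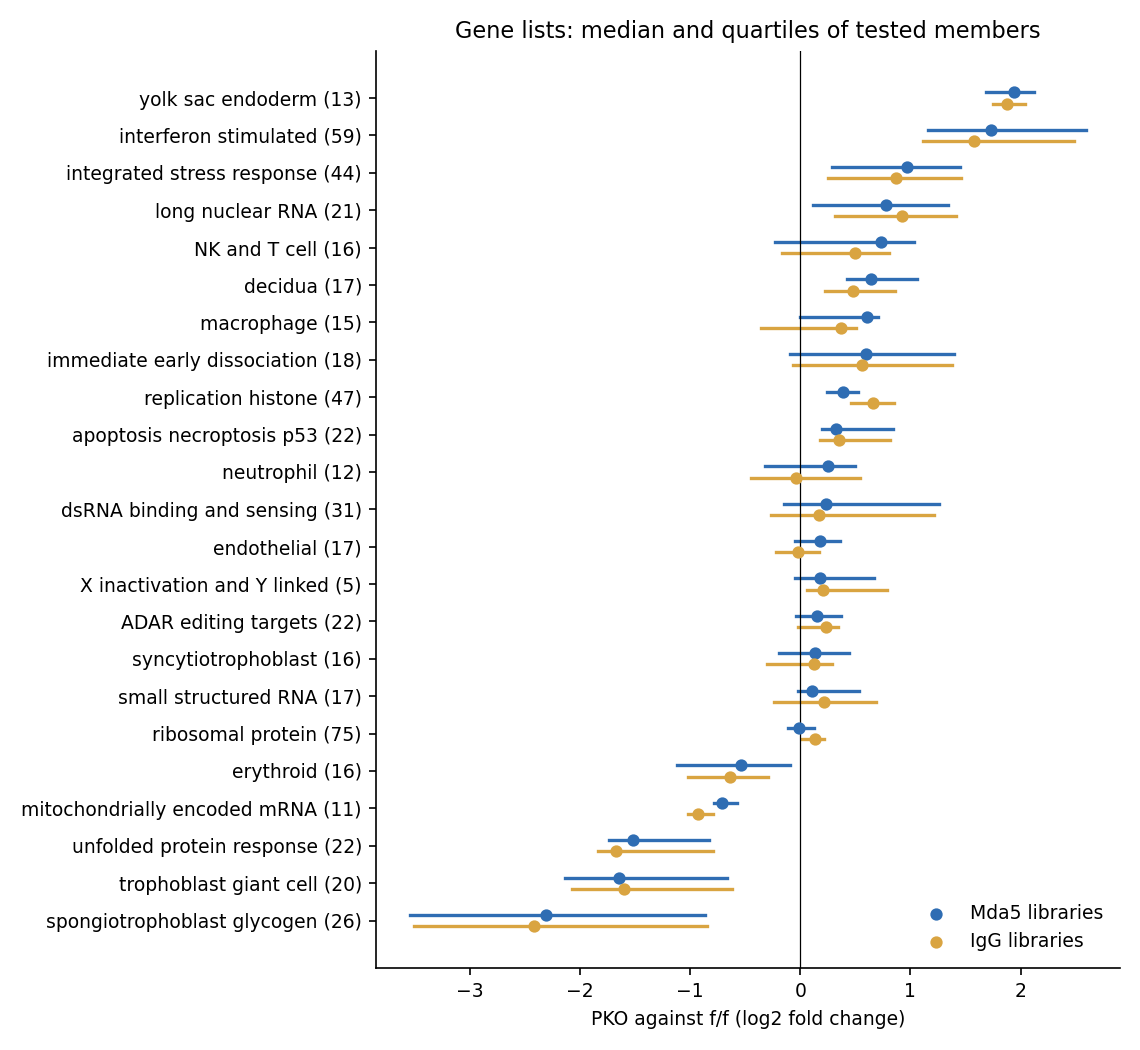
Median (points) and quartiles (bars) of the log2 fold change of PKO against f/f over the tested members of 23 gene lists (all but the interferon genes and the pair of mitochondrial rRNAs), with the number of members in brackets, in Mda5 and IgG libraries. Of the lists shown, yolk sac endoderm and interferon-stimulated genes lie highest, and spongiotrophoblast, giant cell and unfolded protein response genes lowest, in both antibodies.

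In total 6072 genes were higher and 6746 lower in PKO in Mda5 libraries, and 6367 and 6737 in IgG libraries, by edgeR. Scaling to library totals moved the median of all genes from 0.04 to 0.35 in Mda5 and from 0.07 to 0.42 in IgG libraries. It gave 10759 higher and 3273 lower and 12435 and 2909. TMM factors from genes of at least 1 CPM gave 7003 and 5875 and then 8049 and 5262. The distances of the lists from that median stayed almost as they were, at 1.69 for interferon-stimulated and −2.35 for spongiotrophoblast genes in Mda5 libraries. The log2 fold changes in the 2 antibodies, taken from the same placentas, correlated across the 12402 genes of at least 2 CPM at r = 0.963. Across all 26170 tested genes r was 0.759. With 2 placentas per genotype, the p-values measure the spread between these placentas and their libraries only. For each gene that spread was drawn in large part from other genes, with a median prior of 16.4 degrees of freedom beside 4 residual ones. Very small p-values thus do not rest on a gene's own replicates alone. Outside the fits with a block, the 2 libraries of a placenta were also taken as independent.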

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

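Of the tests in this part, those on background reads, the gap between genes of low and of higher level, the share of trophoblast cells and yolk sac tissue, and the fits with a gene length offset or with TMM factors from genes of at least 1 CPM, were chosen after the result was seen.

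The differences of Mda5 enrichment between PKO and f/f are set apart here because the interaction test found that the 2 genotypes differed. By gene the log2 differences were 0.87 for H2-T24, 0.86 for Col4a5, 0.83 for Ksr2, 0.79 for Pax5, 0.78 for Hipk2, 0.78 for Arnt2, 0.77 for Zfp469 and 0.76 for Dnah10, and −1.68 for Slc6a16, −1.33 for Cnpy1, −1.17 for Snhg20, −0.87 for Egfros, −0.86 for Megf11, −0.79 for Pfdn4, −0.76 for Cox17 and −0.62 for Rbm4b. Members of the lists were Ifit1 at 0.56, Oas3 at 0.58, Lgals3bp at 0.35, Dtx3l at 0.34, Mmrn2 at 0.52, Robo4 at 0.50, Kdr at 0.39, Plvap at 0.32, Prf1 at 0.40, Copa at 0.39, Vldlr at 0.34, H4c14 at −0.57, H4c12 at −0.45 and H4c9 at −0.40, with Fn1 at 0.48 and Pappa2 at 0.37 among abundant genes. The lists whose differences passed had medians of 0.088 (interferon-stimulated), 0.088 (double-stranded RNA binding), −0.11 (ribosomal proteins), −0.26 (histones), 0.20 (decidua) and 0.23 (endothelium). None of them passed with an estimated correlation (camera adjusted p = 0.626, 0.626, 0.97, 0.626, 0.626 and 0.0651).

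More genes had a higher (278) than a lower (38) Mda5 enrichment in PKO, and the higher ones spanned a median of 66.7 kb against 9.49 kb for the lower ones. A trend on genomic span as the whole cause is argued against. With each library's trend on span removed in 4 fits, at least 167 genes were still called higher, and 147 to 213 of the 278 were kept. The median difference of the 278 went from 0.41 to 0.36 to 0.37. These fits cannot speak on the length of the transcript, since span includes introns and transcript length was not used. For normalization, library totals left 3.05 times and DESeq2 size factors 9.85 times as many higher as lower calls, both beyond the bound of 3 set beforehand. With TMM factors taken from genes of at least 1 CPM and all 26170 genes tested the ratio was 2 (88 higher and 44 lower). That scaling had not been covered by the bound, so the share of this asymmetry due to scaling cannot be told apart from a difference in recovery. The result also rests on few libraries, with 7 calls without both libraries of a8, 4 without those of b9 and 1612 without the Mda5 library of a3. A difference of the genotypes in what Mda5 binds stays open and was not tested apart from these.

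Genes under 0.25 CPM, 8788 of those tested, were lower with Mda5 (median −0.55 over both genotypes) and higher in PKO (median 0.41 in Mda5 and 0.55 in IgG libraries), and they made up 75.1% of the 2-fold lower calls over both genotypes. Normalization is argued against as the cause, since 1 factor per library moves all genes alike, while the medians of these genes and of the 13679 genes of at least 1 CPM differed by −0.69 over both genotypes and by 0.489 (Mda5) and 0.65 (IgG) between genotypes. A comparison with library totals, set beforehand, says little on the first of these: the median over both genotypes was −0.58, but that scaling moved the median of all genes only from 0.00 to −0.03. It moved the medians between genotypes to 0.71 and 0.90, and those of all genes to 0.35 and 0.42. Background reads over silent genes cannot be told apart from other causes. The 175 olfactory and vomeronasal receptor genes, summed, were higher with IgG in all 4 placentas (IgG to Mda5 ratios of 1.56 in a8, 1.55 in a3 and 1.36 in b2, 10.6 against 8.45 CPM in b9, and a mean ratio of 1.43), and higher in each PKO library (11.1 to 17.2 CPM) than in either f/f library of the same antibody (7.44 to 11.6 CPM). Of the 62 tested ones, however, 50 are themselves under 0.25 CPM, so these sums repeat the pattern on its own members. Their median was −0.68 against −0.54 for the other genes under 0.25 CPM, a difference of −0.139, within the bound of 0.2 set for the test. Genomic DNA, unspliced transcripts and reads from other loci were not told apart, as none was measured.

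Spongiotrophoblast and giant cell genes were lower in PKO while yolk sac endoderm genes were higher. Syncytiotrophoblast genes did not fall with the other trophoblast genes, as their median was 0.14 in Mda5 and 0.13 in IgG libraries. This argues against an equal fall of all trophoblast genes, for the 16 genes of that list. It does not exclude a lower share of all trophoblast cells, since the members went both ways (7 higher and 5 lower, then 7 and 6). How specific these members are to trophoblast was not tested. Dilution by more yolk sac tissue in the PKO samples is argued against as the cause of the fall. It would lower placental genes alike, but the lower quartiles of the syncytiotrophoblast and decidua lists were −0.30 or higher in both antibodies, against giant cell medians of −1.65 and −1.60. The rise itself, with all 13 tested yolk sac endoderm genes called higher in both antibodies, stays open, since tissue carried over at dissection and induction in the placenta were not tested apart. Fewer spongiotrophoblast and giant cells, or lower expression in them, stays open too, with 2 placentas per genotype.

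Chance was tested for the count of genes called between Mda5 and IgG over both genotypes, with genotype as a covariate in every split but that by genotype. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real one, with 14594 genes. The next highest, the split by genotype, gave 7814 in its fit without the covariate, and all others gave 0 by edgeR. That count ignores that the libraries of a placenta are paired. Of the 8 splits that part the libraries of all 4 placentas, the real one called 14594 and the highest other 0, and 8 splits are too few for a share under 0.05. Every split but the real one also leaves the antibody difference in the residual, which by itself keeps its calls few. The second principal component, which parted the antibodies, held 29.2% of the variance. The rank of the real split is therefore no measure of chance.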

How the results depend on the processing

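Halved counts, crossed placentas, the placenta letter, length offsets the fit over genes of at least 1 CPM and TMM factors from those genes were chosen after the data were seen; the form of the offset that removes only the slope was added after the form that also recentres each library. Counts of calls between antibodies and between genotypes stayed within 1.5 times of the values in the report under every alternative run, except 6678 calls in PKO without both libraries of a3 and 7700 in f/f without both of a8, where fewer samples were fitted; leaving out libraries gave at most 12051 and 12227. The interaction's 316 calls became 150 with library totals, 476 with no filter, 928 with DESeq2, 495 with halved counts, 628 with the block and the f/f placentas crossed, 188 over genes of at least 1 CPM, 132 with TMM factors from those genes and 650 at an adjusted p under 0.1. Leaving out single libraries gave 16 (Mda5, b9) to 1612 (Mda5, a3), with 55, 40 and 35 without f/f IgG a8, f/f IgG b9 and f/f Mda5 a8, 74 and 723 without PKO IgG a3 and b2, and 772 without PKO Mda5 b2; without both libraries of a placenta it was 7 (a8), 4 (b9), 809 (a3) and 1177 (b2). A lone library left in a group is assumed there to vary like the other groups, and the cause of these changes was not tested.

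With the placenta as a block the interaction had 432 calls; beyond the genes and list given in the report, the block ended the call of the apoptosis list over both genotypes (camera adjusted p = 0.0549) and changed no other call of a named gene or list. As a random block in limma-voom it gave 12513 and 13334 calls between genotypes in Mda5 and IgG libraries and changed the call of none of the 91 and 65 named genes. With the PKO placentas crossed the interaction had 313 calls. Shares of higher and lower calls moved with centring: library totals and TMM factors from genes of at least 1 CPM gave the splits in the report, and the recentring offset gave 3698 higher and 7905 lower in PKO, 4146 and 7440 in f/f, 4921 and 10132 over both genotypes, 167 and 46 for the interaction, and 7419 and 5652 (Mda5) and 7889 and 5458 (IgG) between genotypes, the offset's own shift of the centre being part of this.

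With an estimated correlation, lists past the threshold went from 20 to 3 in PKO, 17 to 0 in f/f, 6 to 0 for the interaction, 16 to 7 and 16 to 6 between genotypes in Mda5 and IgG libraries, and 19 to 2 over both genotypes, since that test allows for members that vary together. Interaction lists numbered 1 with fry, and 10 to 15 without the Mda5 library of b9 or b2; the ribosomal protein list turned upward without the latter (camera adjusted p = 0.00275), and had 1.21e-28 to 0.0603 without other single libraries.

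Directions of called values turned in these cases. With the recentring offset, alike without and with the block, Irf3 in PKO became −0.005, Ddit4 in f/f −0.016, and Actb −0.119 in f/f and −0.043 over both genotypes. With the slope offset Pappa2 in PKO became 0.025, and 0.026 with the block. With library totals, PKO against f/f became 0.136 for Actb in Mda5 libraries and, in IgG libraries, 0.046 for Adar, 0.005 for Csf1r, 0.205 for Peg10 and 0.094 for Actb, in keeping with the shift of all genes under that scaling; Adar and Peg10 in Mda5 libraries, without a call in the report's fit, became 0.285 and 0.278 and gained one.

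Of the named genes, 58 of 75 in PKO, 52 of 64 in f/f, 3 of 37 for the interaction, 86 of 91 and 59 of 65 between genotypes in Mda5 and IgG libraries, and 18 of 22 over both genotypes kept direction and side of the threshold in all alternatives. The interaction genes gave 1106 values, of which 285 lost the call, 10 gained one and 0 reversed. Depth limits few of these values; the rare interferon transcripts, the smallest at 0 counts in f/f, are bounded by it. Pseudocount alternatives were not run because the values are counts.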

Other observations

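The gene families here, the RNA classes and the tests on Ifih1 were chosen after the data were seen; the test of scaling with Mda5 was set before.

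Gene families were counted by name, without an enrichment test. Of those tested, 24 of 25 prolactin, 4 of 13 Psg, 4 of 7 cathepsin, 2 of 15 Ceacam and 2 of 11 guanylate-binding protein genes are also in the lists. All 13 tested Psg genes, pregnancy-specific glycoproteins of trophoblast, were lower in PKO in both antibodies (median log2 fold change −3.42 in Mda5 and −3.51 in IgG libraries), as were 21 of 25 genes of the prolactin family (−1.40 and −1.37, with 1 and 0 higher) and 6 and 7 of 7 placental cathepsins (−2.28 and −2.31). Of 15 Ceacam genes 9 were lower with each antibody, with 4 higher in Mda5 and 2 in IgG libraries. Guanylate-binding protein genes, induced by interferons, were higher for 9 of 11 (1.37 and 1.27), and major histocompatibility class I genes for 14 and 16 of 27 (0.92 and 1.01), with 3 and 2 lower. The medians of these families kept their signs with library totals and with TMM factors from genes of at least 1 CPM.

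Some extracellular matrix genes had a higher ratio of Mda5 to IgG in PKO than in f/f, a grouping made after the calls were seen and not tested for enrichment. The difference rose with genomic span over 11968 protein-coding genes (Spearman's rho 0.32), and these families were not counted with the length offset. Of 44 collagen genes, 24 were lower and 0 higher with Mda5 in f/f by edgeR (median −0.28), while in PKO 16 were lower and 7 higher (17 and 3 with library totals, and 19 and 1 with TMM factors from genes of at least 1 CPM). The interaction called 10 higher and 0 lower (median 0.30), among them Col1a1 at 0.70 and Col3a1 at 0.66. These 2 genes were lower with Mda5 in both genotypes, at −0.57 and −0.51 in PKO and −1.27 and −1.17 in f/f. Their difference is thus a weaker depletion in PKO. Adamts proteases had 6 of 18 and laminins 4 of 11 with a higher difference. With library totals the higher calls were 6 collagen, 2 Adamts and 3 laminin genes, and with TMM factors from genes of at least 1 CPM 3, 1 and 3. Without the Mda5 library of b9 the interaction had 16 calls over all genes. Nuclear genes of respiratory complex I were enriched with Mda5 for 44 of 50 in PKO and 46 of 50 in f/f (medians 0.59 and 0.80), against the depletion of the mitochondrially encoded mRNAs. Among RNA classes, 95 of 150 tested miRNA genes and 52 of 119 snoRNA genes were lower with Mda5 in PKO and 0 higher by edgeR, and 75 and 20 in f/f. These classes are rare, with median levels of 0.074 and 0.063 CPM, and rare genes were lower with Mda5 as a whole. The class medians in PKO were −1.899 and −1.428, against −0.772 for all tested genes under 0.1 CPM. An effect of class apart from low level was not tested.

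Ifih1 mRNA was the most enriched of the 59 interferon-stimulated genes with Mda5 in both genotypes, by 0.72 in PKO and 0.44 in f/f on the log2 scale above the next gene, Bst2 (0.438 being the smaller). A candidate explanation is recovery of Ifih1 mRNA through newly made Mda5 protein on the antibody, a hypothesis found on these data; Mda5 binding to its own mRNA remains open, and no library without translation was analysed here.

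If recovery scaled with the amount of Mda5, the 183 genes enriched at least 2-fold over both genotypes at 1 CPM or more would differ upward in PKO, where Ifih1 mRNA was higher. Their median difference was −0.079 (quartiles −0.22 and 0.11), with 1 called higher and 5 lower, so the predicted rise relative to other genes was not seen. This cannot decide the question, since TMM normalization removes a rise shared by all genes and the amount of Mda5 protein was not measured. The 183 genes were chosen by their ratio alone and 39 of them are histones, so they were not shown to be bound by Mda5.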
